A study of Mus musculus with 12 samples.

How the data were processed

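RNA sequencing was deposited for 12 libraries of a mouse glioma line, PIC496-3, in 4 groups of 3. The labels give the genotype Cas9, Pik3ca-H1047R, Idh1-R132H, Trp53KO and AtrxKO. Groups received DMSO or 1 µM AG120 for 5 days, each alone or with 10 ng/mL IFNγ over the last 2 days, and are called DMSO, IFNγ, AG120 and AG120+IFNγ here. Total RNA was depleted of ribosomal RNA and made into a directional library, per the labels. The labels do not state whether the replicates of a group came from separate cultures, so the spread between replicates may be that of a single culture. They give both spheroid and monolayer culture, and which applies to these libraries is not clear.

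The deposited gene table holds estimated read counts (expected counts) per gene symbol, not normalised: 67.8% of its values are whole numbers, and 8326 of its 36255 genes are at 0 in all 12 libraries. The deposited repeat table holds estimated counts (expected counts) per repeat copy, with 98.2% of values whole. It has 2046079 entries by copy and read strand over 1536399 distinct copies. Trimmomatic 0.36, FastQC 0.11.7, kallisto 0.46.0 and the mouse build mm10 were named by the authors, per the submitters' processing notes, which give no role for each. The tool settings and the repeat annotation behind the repeat table, and the use of read strand for the gene table, are not given in the sources used here. Near-identical genes such as Tgtp1 and Tgtp2, the H2 genes, overlapping genes and copies of one repeat subfamily may therefore share reads.

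Counts were rounded, and all 24 sample columns were used. Structural RNA entries (rRNA, tRNA, the 7SL and 7SK families and the like), 9.2 to 23.4% of the repeat counts, were kept out of the repeat tests, which leaves 1096 transposable subfamilies. Gene positions, exons and gene types come from GENCODE M21, matched by symbol. Repeat coordinates start at 0 in the deposited table and are given here from 1. Gene counts per library came to 30.09 to 54.63 M and transposable element counts to 4.99 to 13.56 M. For a group at 0 in every library, a fold is a lower bound against a floor of 3 counts over the group. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

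Each comparison was tested in edgeR 4.0.16 (quasi-likelihood F test, robust, filterByExpr with a minimum count of 10 and a total of 15, TMM factors) in 1 fit of all 12 libraries, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The comparisons were AG120 against DMSO, IFNγ against DMSO, AG120+IFNγ against IFNγ, AG120+IFNγ against AG120, and the interaction, the difference between the AG120 effects with and without IFNγ. Repeats were tested the same way as 1050 subfamily sums and 150853 single copies, the latter with at least 20 counts in all, and took library sizes and TMM factors from the gene table so that a change of many subfamilies together is not scaled away. CPM means counts per 1e6 TMM-scaled gene counts. Totals of repeat classes were compared by a two-sided exact permutation test on the log2 scale, stratified by the other treatment (400 arrangements, smallest possible p 0.005), adjusted over 5 totals.

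Gene lists, 30 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), and 29 had the 3 tested genes needed. The lists are MHC class I presentation, immunoproteasome, MHC class II presentation, IFNγ GTPases, type I interferon effectors, interferon receptors with JAK-STAT and IRF genes, interferon ligands, chemokines and cytokines, checkpoint ligands, cytosolic DNA sensing, RNA sensing, DNA methylation, retroelement restriction, methylation-silenced germline genes, IDH and 2-hydroxyglutarate metabolism, histone demethylases, cell cycle, p53 targets, neural stem, astrocyte, oligodendrocyte, neuron, leukocyte, endothelial and mural, fibroblast, cholesterol synthesis, ATF4 and unfolded protein response, hypoxia and glycolysis, mitochondrially encoded genes, and histones. Counts of list members are over all genes tested. Counts adjusted over the list alone are given where they differ. Values with an estimated correlation are given where the call is lost. The smallest adjusted p values of lists rest on the preset correlation. For type I effectors in the interaction, for example, camera gave 6.32e-06 with an estimated correlation in place of 7.58e-39.

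The tests, lists and the rule for named genes were fixed before the data were examined. The rule takes focus genes and subfamilies, the 8 genes rising and falling most per comparison (6 for the interaction) among those called, with mean log2 CPM of at least 1 and, outside the interaction, with no overlap of the groups, up to 4 members per list with the smallest adjusted p, and likewise 5 subfamilies and 3 copies with a mean of at least 10 counts. A gene of the focus list is not reported here. For 3 libraries against 3, chance alone keeps 10% of genes free of overlap.

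The fits were tested on simulated counts built on the levels of the DMSO and IFNγ libraries and the fitted spread. In each, 200 features were changed, of 17535 genes, 1042 subfamilies or 16934 copies. That is fewer than AG120 against DMSO called in the data at each level, so the shares called need not hold for that test. Of genes changed 1.25-fold, 54% were called, and of genes changed 2-fold, 82%, with 6.8% false calls. For subfamilies the shares were 73% and 97%, with 5.6% false calls. For single copies they were 0 and 4%, so an uncalled copy says little. A simulated list moved 1.5-fold was called, but in independent noise per gene and not in counts, so the preset correlation was not tested. Alternatives were library size alone, DESeq2 size factors, DESeq2 1.42.0 as the tool, other low-count filters, only the groups compared, scaling on the repeat counts, copies outside annotated genes, a replicate block, fry, camera with an estimated correlation, and each library left out in turn. A minimum log2 fold change of 1 for subfamilies, the gene tests without genes whose exons overlap rising LTR subfamilies, and class totals without 1 FordPrefect copy were added after seeing the data. R 4.3.3, bedtools 2.31.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.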

Results

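RNA was sequenced from the mouse glioma line PIC496-3, which carries Idh1-R132H, a mutant isocitrate dehydrogenase that makes 2-hydroxyglutarate. Cells were grown with DMSO or with AG120 (ivosidenib, an inhibitor of mutant IDH1) for 5 days, and with or without interferon gamma (IFNγ) for the last 2 days. Each of the 4 groups, DMSO, IFNγ, AG120 and AG120+IFNγ, has 3 libraries. Gene counts came to 38.84 to 48.96 M with DMSO, 43.04 to 54.63 M with IFNγ, 31.31 to 45.17 M with AG120 and 30.09 to 34.16 M in the libraries labelled AG120+IFNγ. Changes are log2 fold changes from edgeR with adjusted p values, n = 3 per group, and levels are CPM (scaled counts) as mean ± SD. The ± after a log2 change is an approximate SE based on the edgeR fit. It is too small for large folds from a group with few counts, so such folds are less certain than it shows. Psmb9, for example, spanned 0.098 to 0.498 CPM among the DMSO libraries. Positions are on mm10. The 10 most abundant genes took 7.09 to 7.31% of counts in libraries without AG120 and 12.97 to 15.09% in those with it, and the mitochondrially encoded share was 2.2 to 2.46% against 1.3 to 1.57%.

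With AG120 alone, the question, from the series title, was whether inhibiting mutant IDH1 switches on innate immune signalling through DNA sensing. Interferon-stimulated genes rose strongly without added interferon. Cxcl10, a chemokine that draws T cells (chromosome 5, 92346638 to 92348889), went from 0.963 ± 0.0422 to 235 ± 9.03 CPM, a log2 change of 7.92 ± 0.05 (adjusted p = 7.52e-61). Isg15, a ubiquitin-like antiviral modifier, rose by 7.49 ± 0.09 and Ifit1, which binds viral RNA, by 7.99 ± 0.07. Germline genes and endogenous retroviruses rose too.

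All 33 tested type I interferon effectors rose (median 5.63, adjusted p = 3.44e-19), among them Oasl2 (8.87 ± 0.06), Ifit3 (9.69 ± 0.08) and Usp18 (7.44 ± 0.07). Of 20 IFNγ GTPases and effectors, which attack intracellular pathogens, 19 rose (median 5.85, adjusted p = 2.1e-13). Tgtp2 was at least 1180-fold higher, Tgtp1 at least 297-fold higher, and Ifi47 rose by 10.38 ± 0.23. Antigen presentation rose with them: 17 of 17 MHC class I genes (median 3.37, adjusted p = 6.22e-11), including H2-K1 (3.70 ± 0.03) and its light chain B2m (3.37 ± 0.03). So did 5 of 5 immunoproteasome genes (median 2.38, adjusted p = 0.000472), including Psmb9 (5.84 ± 0.19). Of 13 MHC class II genes 10 rose (median 0.86, adjusted p = 0.0187, and adjusted p = 0.121 with an estimated correlation). Ciita, the master activator of class II genes, moved by 0.52 ± 0.11 (adjusted p = 4.08e-05). Chemokines and cytokines rose in 21 of 22 cases (median 2.82, adjusted p = 3.51e-08), with Ccl2 at 4.56 ± 0.16 and Ccl5 at 3.41 ± 0.17. Of 20 receptor, JAK-STAT and IRF genes 17 rose and 2 fell (median 1.01, adjusted p = 4.28e-06), and Irf7, which amplifies type I interferon, rose by 5.88 ± 0.06. The checkpoint ligand Cd274 (PD-L1) rose by 2.98 ± 0.13 among 7 of 12 ligands that rose and 2 that fell (adjusted p = 0.018, and adjusted p = 0.0627 with an estimated correlation).

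Of 22 cytosolic DNA sensing genes 14 rose and 3 fell (median 1.03, adjusted p = 0.0047), including the DNA sensor Cgas (2.09 ± 0.14, adjusted p = 3.18e-18) and its adaptor Sting1 (2.85 ± 0.04, adjusted p = 1.27e-45). RNA sensing genes rose in 11 of 13 cases and fell in 1 (median 2.43, adjusted p = 4.92e-06), including Ddx58 (RIG-I, 4.29 ± 0.04) and Ifih1 (MDA5, 4.71 ± 0.05). Both lists share members with the type I effectors, such as Zbp1 for DNA and Dhx58 for RNA sensing. IFNγ alone also raised the DNA list (camera adjusted p = 0.00157) and the RNA list (camera adjusted p = 4.82e-06). With IFNγ alone the medians of these lists were smaller, at 0.19 for DNA and 0.48 for RNA sensing. Whether the rise of the 2 lists with AG120 is separate from the interferon response was not tested. That rise does not show that sensing was active. Among interferon ligands only Ifnk passed the count filter, with a change of -0.17 ± 0.54 (adjusted p = 0.798), so that list was not tested. Ifnb1, encoding interferon beta, had 0 counts in all DMSO libraries and 2 to 3 counts per library with AG120.

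All 26 tested germline genes that DNA methylation silences in other tissues rose (median 5.01, or 4.70 with genes at 0 in a group set at their bound, adjusted p = 9.78e-11). Dazl, a germ cell RNA-binding protein (chromosome 17, 50279395 to 50293636), was at least 929-fold higher, at 19.8 ± 1.5 CPM, and Mov10l1, a piRNA pathway helicase, rose by 8.95 ± 0.12. Other large rises were Gm10693 (11.46 ± 0.20), Tuba3b (9.93 ± 0.23), Dpep3 (9.87 ± 0.23) and Serpinb1c (9.84 ± 0.21). DNA methylation genes went both ways, 8 up and 6 down of 16 (adjusted p = 0.753): the demethylating enzyme Tet2 fell by 0.50 ± 0.03 and the methyltransferase Dnmt1 rose by 0.21 ± 0.02. Retroelement restriction genes also split, 13 up and 11 down of 26 (adjusted p = 0.539), with Apobec3 at 2.04 ± 0.03 and Cbx5 at -0.82 ± 0.02. The exons of Apobec3 hold an RLTR4_Mm copy, a rising LTR subfamily. Histone demethylases that use alpha-ketoglutarate fell in 14 of 19 cases and rose in 2 (median -0.23, adjusted p = 0.00312). Genes of IDH and 2-hydroxyglutarate metabolism went both ways, 9 up and 12 down of 23 (median -0.11, mean 0.02, adjusted p = 0.354), with Idh1 at -0.41 ± 0.02.

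Hypoxia and glycolysis genes all rose, 22 of 22 (median 2.30, adjusted p = 2.73e-17). The angiogenic factor Vegfa went from 25 ± 1.1 to 484 ± 7.59 CPM (4.28 ± 0.03) and the glucose transporter Slc2a1 rose by 3.76 ± 0.03. Stress genes of the ATF4 and unfolded protein response rose in 20 of 22 cases and fell in 1 (median 0.73, adjusted p = 3.51e-08), such as Asns (1.41 ± 0.03), which makes asparagine. Fibroblast genes rose in 11 of 12 cases and fell in 1 (median 2.75, adjusted p = 4.16e-05): the collagen Col1a1 rose by 5.88 ± 0.06 and fibronectin, Fn1, by 3.93 ± 0.02. Astrocyte genes rose in 11 of 15 cases and fell in 4 (median 0.38, adjusted p = 0.00972), with the filament protein Gfap at 3.60 ± 0.03. Neural stem genes fell in 11 of 19 cases and rose in 5 (median -0.25, adjusted p = 0.0428, and adjusted p = 0.159 with an estimated correlation), with Egfr at -1.26 ± 0.02 and Sox2 at -0.25 ± 0.02. Cell cycle genes rose in 22 of 32 cases and fell in 5 (median 0.31, adjusted p = 0.000787), with Top2a at 0.61 ± 0.02 and Mki67 at 0.25 ± 0.05.

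Oligodendrocyte genes parted, 9 up and 7 down of 18 (adjusted p = 0.539): the lineage factor Sox10 rose by 5.56 ± 0.08 and Cspg4 by 2.13 ± 0.02. Olig2 fell by 0.80 ± 0.02 and Gpr17 fell 2.38-fold. The p53 target list had 14 up and 8 down of 23 (adjusted p = 0.204), with the cell cycle inhibitor Cdkn1a at 2.92 ± 0.04. Lists without a call were neuron (4 up and 6 down of 17, median 0.09, mean -0.09, adjusted p = 0.651), leukocyte (3 up of 13, adjusted p = 0.539), endothelial and mural (4 up and 2 down of 12, adjusted p = 0.412, with Acta2, smooth muscle actin, at -2.80 ± 0.03) and cholesterol synthesis (8 up and 7 down of 20, adjusted p = 0.729). Mitochondrially encoded genes fell in 11 of 13 cases (median -1.28, adjusted p = 0.000569, and adjusted p = 0.327 with an estimated correlation), such as mt-Cytb (-1.36 ± 0.08). Histone genes fell in 14 of 18 cases (median -0.35, adjusted p = 0.000432, and adjusted p = 0.216 with an estimated correlation), such as H1f5 (-0.47 ± 0.02). Among genes within the level and overlap limits for naming, the largest falls were in Rai2 (-4.76 ± 0.25), Trdn (-4.63 ± 0.35), Rgr (-4.04 ± 0.21), Atoh8 (-3.95 ± 0.15) and the polarity gene Crb2 (-3.93 ± 0.12). Among genes edited in the line, Trp53 RNA stood 0.52 ± 0.04 higher and Atrx 0.41 ± 0.03 lower, with Pik3ca at -0.25 ± 0.02.

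In all, 11769 of 18140 tested genes passed, 5982 higher and 5787 lower, and 2978 changed at least 2-fold, 2294 of them higher. Adjusted over the list alone, counts were the same except 10 rising IDH metabolism genes, 13 falling mitochondrial genes and 2 rising leukocyte genes. Of 29 lists, 20 passed, and 15 did with an estimated correlation.

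**Figure D1:**
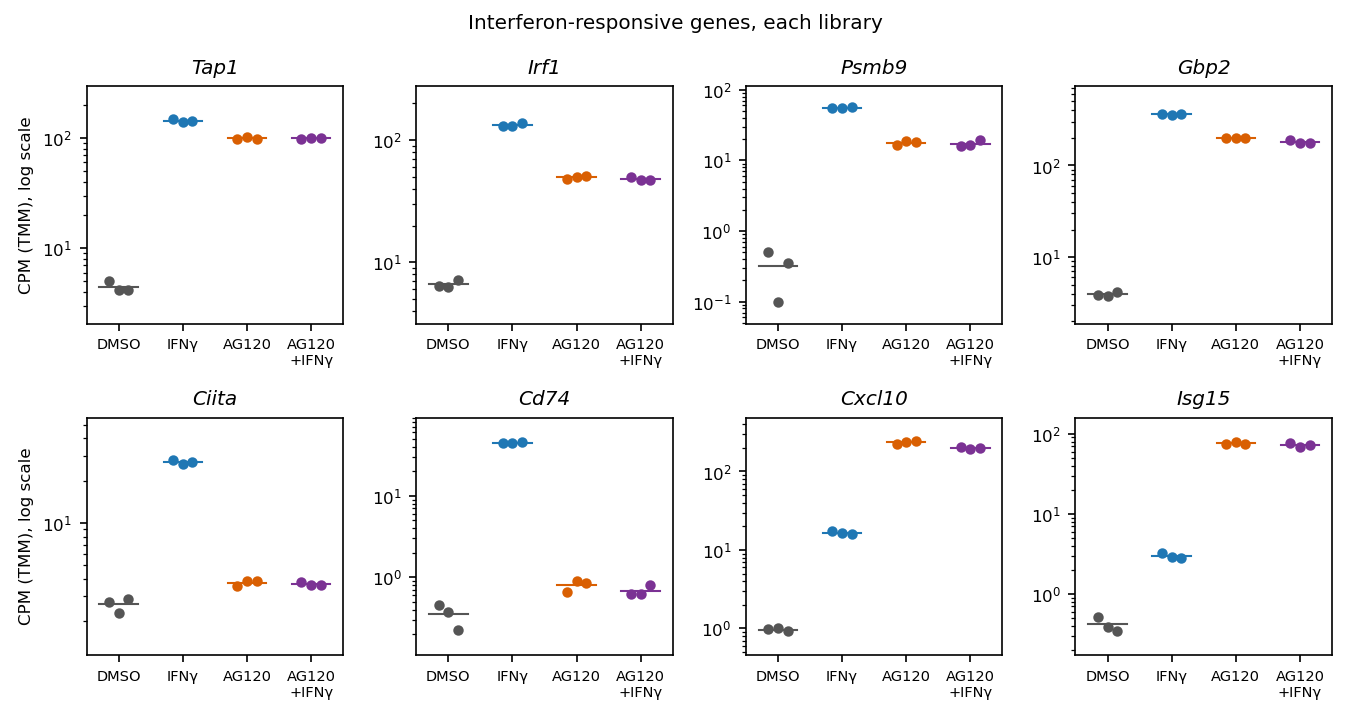
CPM (log axis) of 8 interferon-stimulated genes in each library, by group, with lines at group means. Cxcl10 and Isg15 were highest in the groups with AG120, while Ciita and Cd74 were high with IFNγ alone, at 27.3 and 44.8 CPM, and stayed at 3.7 and 0.686 CPM in the libraries labelled AG120+IFNγ.

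Transposable elements were read alongside genes, since retroviral RNA and DNA can set off innate sensors. Endogenous retroviruses of the IAP family rose most with AG120. IAPEz-int, the IAP internal region, rose from 2389 ± 14.5 to 152800 ± 2520 CPM, a 64-fold rise, and by 6.20 ± 0.02 in log2 over copies outside annotated genes. Its long terminal repeats IAPLTR1a_Mm (128-fold) and IAPLTR1_Mm (5.45 ± 0.02) rose too, as did IAPEy-int (5.28 ± 0.04), MMERGLN-int (3.75 ± 0.02) and MMVL30-int (2.42 ± 0.03). RLTR10C stood at 0.04 ± 0.04 (adjusted p = 0.456), and at 0.17 ± 0.07 over copies outside genes (adjusted p = 0.0305). Of 639 LTR subfamilies 323 rose and 43 fell (202 and 133 when libraries were scaled on repeat counts), and 59 rose at least 2-fold. The SINE subfamilies moved little: 24 of 37 fell and 2 rose, while B1_Mm (-0.04 ± 0.01) and B2_Mm2 (-0.04 ± 0.01) turned to 0.01 ± 0.03 and 0.20 ± 0.02 over copies outside genes. L1_Mus1, a LINE, rose by 0.21 ± 0.02, and by 1.24 ± 0.03 over copies outside genes. MER50B (-1.38 ± 0.05) and MER49 (-1.06 ± 0.22) fell most.

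In all, 583 of 1050 subfamilies passed with AG120 against DMSO, 465 higher and 118 lower (281 and 270 when scaled on repeat counts, 477 and 20 of 872 over copies outside genes). Of single copies, 19596 rose and 9391 fell of 150853, and 63.6% of the rising copies were LTR elements and 51.9% lay between genes. An IAPEz-int copy at chromosome 12, 8407263 to 8408076, between genes, was at least 7520-fold higher, at 153 ± 63.8 CPM with AG120. Another at chromosome 13, 5278429 to 5282046, was at least 5630-fold higher, at 121 ± 2.43 CPM. Copies of a subfamily may share reads, so these folds may not belong to the copy named.

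LTR counts, scaled to gene counts like CPM, were 27700 ± 225 with DMSO, 26330 ± 189 with IFNγ, 199000 ± 2740 with AG120 and 209600 ± 2110 in the libraries labelled AG120+IFNγ, which is 22.3, 22.7, 64.9 and 66.3% of repeat counts. Over both strata the AG120 effect on the log2 scale was 2.919 for LTR elements, 1.373 for all repeats, 0.132 for LINEs, -0.066 for SINEs and 1.217 for DNA transposons, each with an exact permutation p of 0.005, the smallest these arrangements can give. As a share of repeat counts, which the LTR rise lowers for other classes, the LINE effect was -1.241 and the SINE effect -1.439 (adjusted exact p = 0.00667 each). The DNA transposon effect was then -0.156 (adjusted exact p = 0.1). Scaled to gene counts, the LINE effect was 0.014 (adjusted exact p = 0.645) without TMM factors. The DNA transposon effect was -0.021 (adjusted exact p = 0.295) without a single FordPrefect copy in an exon of Gm26917 (chromosome 17, 39842998 to 39843163). That copy held 53.2% of DNA class counts with DMSO and 83.4% in the libraries labelled AG120+IFNγ. The IFNγ effect was -0.176 for LINEs and -0.107 for SINEs (adjusted exact p = 0.0125 each, but 0.06 and 0.1 as a share of repeat counts), and 0.001 for LTR elements, -0.027 for all repeats and 0.131 for DNA transposons (adjusted exact p = 0.96, 0.375 and 0.292). These last values average opposite signs without and with AG120: -0.073 and 0.075 for LTR elements, -0.098 and 0.045 for all repeats, and -0.177 and 0.439 for DNA transposons. Without the FordPrefect copy the IFNγ effect on DNA transposons was -0.131 (adjusted exact p = 0.01).

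**Figure D2:**
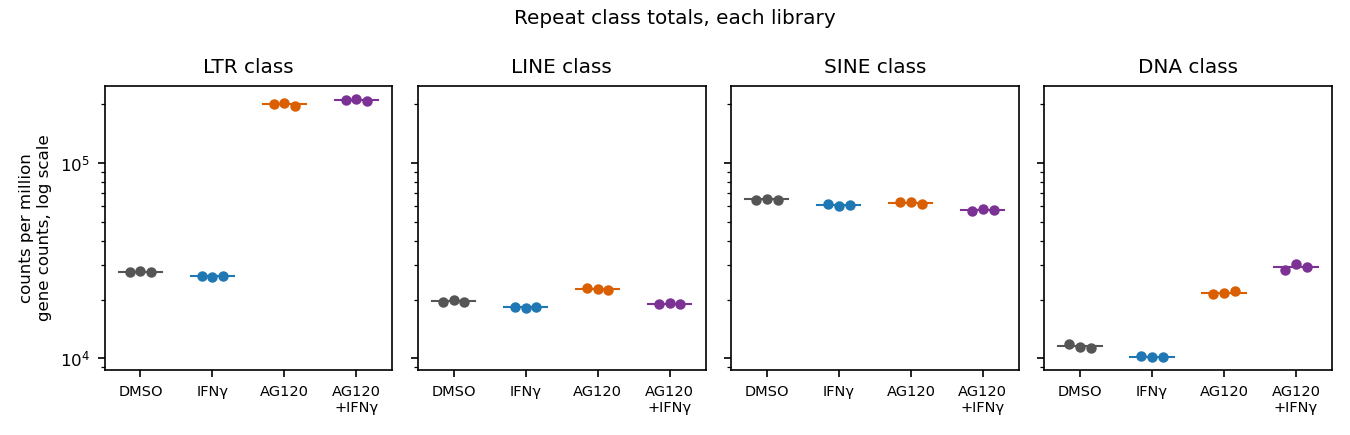
Counts of LTR, LINE, SINE and DNA repeat classes scaled to gene counts (log axis) in each library, by group, with lines at group means. LTR totals sat at 195800 to 211800 in the 6 libraries with AG120 and at 26120 to 27960 in the 6 without.

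IFNγ alone asks what the cytokine does to these cells without the inhibitor. It raised the classical IFNγ programme. Irf1, an interferon-induced transcription factor, rose by 4.33 ± 0.05 (adjusted p = 4.66e-52) and Ciita by 3.38 ± 0.09 (chromosome 16, 10480059 to 10528418, adjusted p = 9.2e-35). The class II chain H2-Aa (chromosome 17, 34282744 to 34287823) went from 0.0382 ± 0.0312 to 53 ± 0.893 CPM (10.42 ± 0.16), and the invariant chain Cd74 rose by 6.96 ± 0.11. The SE given for H2-Aa is too small, since its DMSO level rests on few counts.

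IFNγ GTPases rose in 19 of 20 cases (median 6.84, adjusted p = 4.62e-45): Tgtp2 was at least 10800-fold and Tgtp1 at least 8730-fold higher, Ifi47 rose by 11.83 ± 0.19 and Igtp by 9.10 ± 0.05. MHC class I genes rose in 17 of 17 cases (median 3.54, adjusted p = 1.62e-37), immunoproteasome genes in 5 of 5 (adjusted p = 3.91e-12, Psmb9 at 7.49 ± 0.16) and class II genes in 8 of 13 (median 3.38, adjusted p = 8.21e-11). Type I effectors rose in 28 of 33 cases (median 2.37, adjusted p = 1.14e-36), with Isg15 at 2.81 ± 0.16. Chemokines and cytokines rose in 12 of 22 (median 0.66, adjusted p = 3.21e-09), with Cxcl10 at 4.09 ± 0.07, and receptor, JAK-STAT and IRF genes in 12 of 20 (median 0.14, adjusted p = 5.84e-11), with Irf8 at 4.92 ± 0.10. Checkpoint ligands rose in 5 of 12 (adjusted p = 0.00395), including Cd274 (3.05 ± 0.12). DNA sensing genes rose in 8 and fell in 1 of 22 (adjusted p = 0.00157), with Zbp1 at 5.14 ± 0.22, Sting1 at 0.61 ± 0.05 and Cgas at 0.20 ± 0.16 (adjusted p = 0.413). RNA sensing genes rose in 8 and fell in 1 of 13 (median 0.48, adjusted p = 4.82e-06). Germline genes had 1 up and 2 down of 26 (adjusted p = 0.461), with Sycp1 at -0.54 ± 0.17.

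Other lists moved by small steps. Cholesterol synthesis rose in 15 of 20 cases (median 0.13, adjusted p = 3.87e-08) and cell cycle in 17 of 32 with 1 fall (median 0.10, adjusted p = 1.68e-06). The ATF4 and unfolded protein response list rose in 12 of 22 with 2 falls (median 0.13, adjusted p = 8.5e-06), IDH metabolism in 12 of 23 (median 0.08, adjusted p = 8.34e-05) and hypoxia and glycolysis in 12 of 22 with 1 fall (median 0.10, adjusted p = 0.00115). Oligodendrocyte genes fell in 8 of 18 with 1 rise (median -0.24, adjusted p = 6.1e-05, Pdgfra at -0.40 ± 0.03), astrocyte genes in 9 of 15 with 4 rises (median -0.16, adjusted p = 0.00951, Slc1a2 at -0.48 ± 0.02) and histone demethylases in 10 of 19 with 1 rise (median -0.08, adjusted p = 0.00286). Calls lost with an estimated correlation were DNA methylation (2 up and 6 down of 16, adjusted p = 0.03, and adjusted p = 0.0728 with an estimated correlation), fibroblast (2 down of 12, adjusted p = 0.03, and adjusted p = 0.0622 with an estimated correlation, Fn1 at -0.63 ± 0.02) and histones (7 up and 1 down of 18, adjusted p = 0.00987, and adjusted p = 0.325 with an estimated correlation). No call was made for retroelement restriction (6 up and 5 down of 26, adjusted p = 0.117), p53 targets (7 up and 2 down of 23, adjusted p = 0.116), neural stem (5 up and 7 down of 19, adjusted p = 0.106), neuron (1 up and 2 down of 17, adjusted p = 0.258) or endothelial and mural genes (2 up and 2 down of 12, median -0.10, camera direction up, adjusted p = 0.805). In the leukocyte and mitochondrial lists edgeR called 0 of 13 genes each, with 0 under an unadjusted p of 0.05 and 0 by DESeq2 (adjusted p of the lists 0.476 and 0.461). Among genes within the level and overlap limits for naming, the largest falls were small, with Grin2c, an NMDA receptor subunit, at -0.94 ± 0.17 and Frem2 at -0.79 ± 0.03. Other called genes fell at least 2-fold.

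In all, 4522 genes passed, 2394 higher and 2128 lower, and 260 changed at least 2-fold, 238 of them higher. Of 29 lists, 21 passed, and 18 did with an estimated correlation. Adjusted over the list alone, counts differed by at most 3 genes in any list, such as 20 rising cell cycle genes, 10 rising histone genes and 0 germline genes (edgeR, with 3 germline genes under an unadjusted p of 0.05 and 2 called by DESeq2). Among repeats, 369 subfamilies passed, 24 higher and 345 lower, but 52 higher and 20 lower when scaled on repeat counts, and 10 higher and 48 lower over copies outside genes. MER73, an ERVL repeat, rose by 3.19 ± 0.12, and by 3.75 ± 0.23 outside genes, while RLTR13D3 (1.10 ± 0.07) and RLTR34D_MM (0.78 ± 0.07) turned to -0.10 ± 0.22 and -0.13 ± 0.17 there. IAPEz-int moved by 0.06 ± 0.01. Single copies rose in 515 cases and fell in 82, and the largest rises lay in exons of induced genes, such as an MTE2b copy in Iigp1 (chromosome 18, 60391347 to 60391623, at least 551-fold higher).

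AG120+IFNγ against AG120 asks what IFNγ adds once mutant IDH1 is inhibited. The interferon genes named next were not called higher than with AG120 alone. Ciita stood at 3.7 ± 0.111 against 3.76 ± 0.186 CPM (-0.02 ± 0.11, adjusted p = 0.951), with Irf1 at -0.04 ± 0.04 (adjusted p = 0.565) and Psmb9 at -0.04 ± 0.10 (adjusted p = 0.869). Cd74 was at 0.686 ± 0.107 CPM and H2-Aa at 0.238 ± 0.14 CPM. Of the 238 genes that IFNγ alone raised at least 2-fold, 2 were called higher (0.8%) and 50 lower, with a median of -0.12 where IFNγ alone gave 2.55, or 2.47 with genes at 0 in a group set at their bound.

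IFNγ GTPases fell in 15 of 20 cases and rose in 1 (median -0.28, adjusted p = 1.25e-08), led by Tgtp1 (-0.85 ± 0.18) and Tgtp2 (-0.66 ± 0.05), and type I effectors fell in 17 of 33 (median -0.20, adjusted p = 3.12e-06), such as Ifit3 (-0.40 ± 0.03). Retroelement restriction fell in 5 of 26 (adjusted p = 0.000629, Slfn8 at -0.54 ± 0.08), DNA sensing in 2 of 22 (adjusted p = 0.00477, Samhd1 at -0.17 ± 0.03) and RNA sensing in 3 of 13 (adjusted p = 0.0351, and adjusted p = 0.0935 with an estimated correlation). Hypoxia and glycolysis rose in 20 of 22 (median 0.19, adjusted p = 1.53e-24), led by Slc2a1 (0.46 ± 0.02) and Ndrg1 (0.41 ± 0.02). Cholesterol synthesis rose in 14 of 20 (median 0.09, adjusted p = 1.52e-09) and histone demethylases in 9 of 19 (median 0.07, adjusted p = 1.76e-05). The ATF4 list rose in 9 of 22 (adjusted p = 0.00476, and adjusted p = 0.0579 with an estimated correlation) and histones in 3 of 18 (adjusted p = 0.0407, and adjusted p = 0.559 with an estimated correlation). The metal-binding Mt1 (0.58 ± 0.12) and Mt2 (0.55 ± 0.09) rose, as did Rai2 (1.70 ± 0.39) and the pseudogene CT010467.2 (0.60 ± 0.05), at 5.59 to 5.79% of gene counts against 3.68 to 4.12% with AG120. Fosb, an AP-1 subunit, fell by 0.95 ± 0.09 and Olfr479 by 1.15 ± 0.18.

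Calls by edgeR were 0 in 6 further lists. For class II (13 genes), the immunoproteasome (5), germline (26) and mitochondrial genes (13), 1 gene each had an unadjusted p under 0.05, and DESeq2 called 1 mitochondrial gene and 0 in the others. For IDH metabolism (23) and fibroblast genes (12), 4 and 2 genes had such a p, and DESeq2 called 2 and 0. The mitochondrial list had adjusted p = 0.0228, and adjusted p = 0.559 with an estimated correlation, and the others 0.222 to 0.636. The remaining 13 lists had adjusted p from 0.0808 to 0.872 and at most 6 called genes each: class I (2 down of 17), receptor, JAK-STAT and IRF (1 down of 20), chemokine (2 down of 22), checkpoint (1 up of 12, median 0.01, mean -0.09), DNA methylation (2 up of 16), cell cycle (3 up of 32), p53 (2 up and 1 down of 23), neural stem (3 up and 1 down of 19), astrocyte (3 up and 3 down of 15), oligodendrocyte (1 up of 18), neuron (1 up and 1 down of 17, median -0.01, mean 0.01), leukocyte (1 up of 13) and endothelial genes (1 up of 12).

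In all, 1294 genes passed, 828 higher and 466 lower, and 27 changed at least 2-fold. The balance of directions follows the scaling: 298 higher and 1996 lower with library size alone, 1263 and 352 with DESeq2 size factors, and 82.6% of 1414 higher in DESeq2. The count was 765 without AG120 replicate 1 and 770 without AG120 replicate 2. Adjusted over the list alone, counts moved, for example, to 16 falling GTPases, 19 falling type I effectors, 12 rising histone demethylases and 21 rising hypoxia genes, and to 6 rising and 2 falling DNA methylation genes. Of 29 lists, 11 passed, and 7 did with an estimated correlation.

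**Figure D3:**
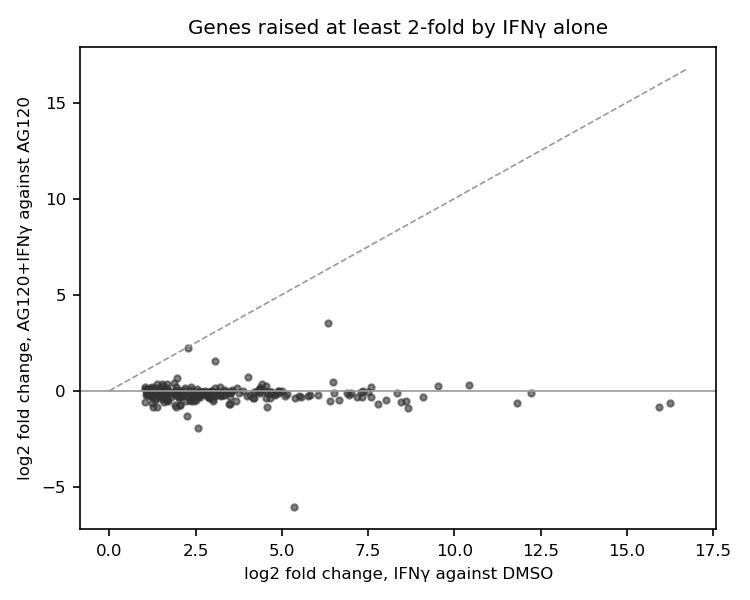
Log2 fold change of AG120+IFNγ against AG120 for the 238 genes raised at least 2-fold by IFNγ alone, against their log2 fold change with IFNγ alone, where the dashed line marks equal change. The median is -0.12 on the vertical axis against 2.55 on the horizontal axis, and 2 genes were called higher and 50 lower.

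Of the repeats, 9 subfamilies rose and 574 fell in AG120+IFNγ against AG120, and 4 rose and 117 fell of 872 over copies outside genes. When scaled on repeat counts 139 rose and 63 fell, with LTR subfamilies turning from 7 up and 299 down to 85 up and 12 down, and SINEs from 34 down to 29 up. Repeat counts outside the LTR class were 51450 ± 537 CPM in introns against 59430 ± 703 with AG120, and 46320 ± 1010 CPM in exons against 38420 ± 264. The exon counts include the single FordPrefect copy in Gm26917, with 83.4% of DNA class counts in the libraries labelled AG120+IFNγ. That class stood at 29380 ± 892 CPM against 21670 ± 433 with AG120. In log2 the class rose by 0.439, but it moved by -0.182 without this copy. Exon counts without this copy were not computed, so the exon difference may be that of 1 copy. IAPEz-int stood 0.11 ± 0.01 higher, MERVL-int at -0.16 ± 0.02 turned to 0.05 with repeat scaling, and FordPrefect at 0.60 ± 0.04 turned to -0.24 ± 0.26 outside genes. Single copies rose in 24 cases and fell in 164 (84 and 38 when scaled on repeat counts), 188 in all, against 89 without AG120 replicate 1, 92 without AG120+IFNγ replicate 1 and 108 without AG120+IFNγ replicate 3. An RLTR13A3 copy in an intron of Ereg was at least 50.8-fold higher (chromosome 5, 91078559 to 91079416).

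AG120+IFNγ against IFNγ asks what the inhibitor does in the presence of IFNγ. Whether IFNγ was present in the libraries labelled AG120+IFNγ was not decided, so falls of IFNγ-induced genes here may reflect its absence. Several class II genes fell: H2-Aa by -7.78 ± 0.13, H2-Eb1 by -6.50 ± 0.16, Cd74 by -6.03 ± 0.11 and Ciita by -2.88 ± 0.09 (adjusted p = 1.83e-32). Type I effectors rose in 33 of 33 cases (median 2.74, adjusted p = 2.23e-15), with Oasl2 at 3.97 ± 0.04 and Isg15 at 4.60 ± 0.06, while Irf1 fell by 1.47 ± 0.04. Dazl was at least 960-fold higher and Tuba3b at least 885-fold higher.

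IFNγ GTPases fell in 15 of 20 cases and rose in 5 (median -1.46, adjusted p = 0.00566), with Igtp at -2.69 ± 0.03. Class II genes fell in 9 of 13 and rose in 3 (median -2.88, adjusted p = 0.0137, and adjusted p = 0.133 with an estimated correlation). Class I genes fell in 11 of 17 and rose in 4 (adjusted p = 0.083), with their activator Nlrc5 at -2.62 ± 0.05, and immunoproteasome genes fell in 5 of 5 (median -0.40, adjusted p = 0.083). Cd274 stood at 0.05 ± 0.09 (adjusted p = 0.694). Chemokines rose in 18 of 22 and fell in 2 (median 1.88, adjusted p = 9.2e-05), with Cxcl10 at 3.59 ± 0.03, and RNA sensing genes rose in 12 of 13 and fell in 1 (median 1.44, adjusted p = 1.41e-05). Germline genes rose in 26 of 26 (median 4.45, adjusted p = 7.17e-11) and hypoxia and glycolysis in 22 of 22 (median 2.50, adjusted p = 1.3e-17). Rises were also called in fibroblast genes in 11 of 12 with 1 fall (median 2.85, adjusted p = 1.7e-05), astrocyte genes in 12 of 15 with 3 falls (median 0.64, adjusted p = 0.0015) and the ATF4 list in 16 of 22 with 4 falls (median 0.73, adjusted p = 2.8e-05). Cell cycle genes rose in 20 of 32 and fell in 9 (adjusted p = 0.0171, and adjusted p = 0.119 with an estimated correlation). Mitochondrial genes fell in 8 of 13 (adjusted p = 0.0109, and adjusted p = 0.385 with an estimated correlation) and histones in 14 of 18 with 2 rises (adjusted p = 0.00309, and adjusted p = 0.289 with an estimated correlation).

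No call was made for 14 further lists, with adjusted p from 0.0983 to 0.876. DNA sensing had 12 up and 3 down of 22, receptor, JAK-STAT and IRF genes 11 and 4 of 20, checkpoint ligands 6 and 3 of 12, DNA methylation 8 and 5 of 16, retroelement restriction 10 and 11 of 26, IDH metabolism 8 and 12 of 23, histone demethylases 4 and 11 of 19, and p53 targets 13 and 7 of 23. Neural stem genes had 6 up and 11 down of 19, oligodendrocyte genes 9 and 7 of 18, neuron genes 6 and 7 of 17 (median -0.01, mean 0.01), leukocyte genes 3 and 1 of 13, endothelial genes 6 and 2 of 12 and cholesterol synthesis 10 and 8 of 20 (median 0.05, mean -0.04). In all, 11817 genes passed, 5761 higher and 6056 lower (4484 and 7922 with library size alone, which moves the median of all genes from -0.011 to -0.152), and 2957 changed at least 2-fold. Adjusted over the list alone, counts were the same except 6 falling DNA methylation genes, 9 falling cholesterol genes, 15 falling histones, and 2 rising and 0 falling leukocyte genes. Of 29 lists, 13 passed, and 9 did with an estimated correlation.

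Of repeats in this comparison, 488 subfamilies passed, 281 higher and 207 lower (432 and 32 outside genes), with IAPEz-int at 6.05 ± 0.01, IAPLTR1a_Mm at 7.32 ± 0.02 and MER73 at -2.58 ± 0.13. An IAPEz-int copy in an intron of Prkar2b (chromosome 12, 32028391 to 32030961) was at least 13200-fold higher, at 259 ± 27 CPM, though copies of a subfamily may share reads. In all, 18100 copies rose and 9120 fell.

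The interaction tests whether the effect of IFNγ, taken by label, differs with the inhibitor. Whether IFNγ was present in the libraries labelled AG120+IFNγ was not decided. If it was missing, the interaction holds no IFNγ effect with AG120 and largely returns the effect of IFNγ alone with its sign turned. Interferon genes rose less from AG120 to AG120+IFNγ than from DMSO to IFNγ, among them Psmb9 (-7.53 ± 0.21), Gbp2 (-6.65 ± 0.05) and Ciita (-3.40 ± 0.14). The IFNγ effect was lower in 17 of 17 class I genes (median -3.60, adjusted p = 1.59e-37), 5 of 5 immunoproteasome genes (median -2.97, adjusted p = 5.23e-12), 18 of 20 GTPases (median -7.08, adjusted p = 4.24e-46), 28 of 33 type I effectors (median -2.42, adjusted p = 7.58e-39). The same held for 12 of 22 chemokines (adjusted p = 2.24e-08), 8 of 13 class II genes (adjusted p = 2.8e-09). It held for 11 of 20 receptor, JAK-STAT and IRF genes (adjusted p = 7.47e-10), 9 of 22 DNA sensing genes (adjusted p = 5.14e-05) and 8 of 13 RNA sensing genes with 1 higher (adjusted p = 1.78e-06). It was also lower in 6 of 26 restriction genes with 2 higher (adjusted p = 0.00377) and 13 of 32 cell cycle genes with 1 higher (median -0.11, adjusted p = 0.00248). It was higher in 14 of 19 histone demethylases (median 0.17, adjusted p = 3.77e-06), 8 of 18 oligodendrocyte genes with 1 lower (adjusted p = 0.000261), 10 of 22 hypoxia genes with 4 lower (adjusted p = 0.00248), 8 of 15 astrocyte genes with 2 lower (adjusted p = 0.0109) and 2 of 12 fibroblast genes (adjusted p = 0.0109, Fn1 at 0.60 ± 0.03).

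Calls lost with an estimated correlation were checkpoint ligands (3 lower of 12, adjusted p = 0.0168, and adjusted p = 0.0554 with an estimated correlation), DNA methylation (6 higher of 16, adjusted p = 0.014, and adjusted p = 0.0513 with an estimated correlation), IDH metabolism (6 lower of 23, adjusted p = 0.00474, and adjusted p = 0.0559 with an estimated correlation) and mitochondrial genes (median 0.32, adjusted p = 0.0408, and adjusted p = 0.539 with an estimated correlation). No call was made for germline (1 lower of 26), p53 (2 higher and 4 lower of 23), neural stem (8 and 3 of 19), neuron (3 higher of 17), endothelial (1 and 3 of 12, median -0.06, mean 0.08), cholesterol (2 and 5 of 20), ATF4 (2 and 6 of 22), histone (2 and 2 of 18) or leukocyte genes, with adjusted p from 0.0664 to 0.812. In all, 3589 genes passed, 1833 higher and 1756 lower (1283 and 2732 with library size alone, and 61.7% higher in DESeq2), and 292 differed by at least 2-fold, 258 of them lower. Adjusted over the list alone, counts moved by at most 2 genes in any list, to 29 lower type I effectors, 14 lower chemokines and 7 lower cholesterol genes. Of 29 lists, 20 passed, and 16 did with an estimated correlation. Of repeats, 20 subfamilies were higher and 182 lower (94 and 51 when scaled on repeat counts, 7 and 18 outside genes), led by MER73 (-3.65 ± 0.20). Of single copies, 78 were higher and 508 lower.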

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

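All tests of an explanation in this part were chosen after the result was seen; the regroupings of libraries were planned before. The effect of AG120 differed with IFNγ (the interaction test) for 3589 genes, 202 transposable subfamilies and 20 gene lists, which is what drew attention to the values below. For genes, 1 of 100 regroupings of the libraries, the real one, gave as many, and the highest other gave 3179. For subfamilies, 5 of 100 gave as many, with 202 in the real grouping and 238 in the highest other. The others as high for subfamilies exchange DMSO and AG120 in full among the libraries without IFNγ, and the highest other for genes mixes them there. Such regroupings carry the AG120 effect itself, so neither count decides on chance. For pairs of groups, 10 splits are too few for a share under 0.05, and 1 of 10, the real one, gave as many in each. Real and highest other counts for AG120 against DMSO, IFNγ against DMSO, AG120+IFNγ against IFNγ and AG120+IFNγ against AG120 were 11769 and 0, 4522 and 0, 11817 and 0, and 1294 and 7 for genes. They were 583 and 0, 369 and 0, 488 and 0, and 583 and 0 for subfamilies, and 28987 and 0, 597 and 17, 27220 and 0, and 188 and 12 for single copies.

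Among the focus genes, those of the interferon response differed between the effects as follows, in log2: Psmb9 -7.53, Psmb8 -7.11, Gbp2 -6.65, Tap1 -5.01, H2-D1 -4.77, Irf1 -4.38, Cxcl10 -4.33, H2-K1 -4.25, Ifit1 -3.83, B2m -3.60, Ciita -3.40, Cxcl9 -3.25, Cd274 -2.93, Isg15 -2.88, Ifih1 -2.63, Ddx58 -1.79, Irf7 -1.34 and Sting1 -0.75. Smaller differences were Mki67 0.48, Tet2 0.26, Dnmt1 0.15, Atrx 0.13 and Sox2 0.12. Among repeats they were IAPLTR1a_Mm 0.32, IAPLTR2_Mm 0.31, RLTR4_MM-int 0.23, RLTR4_Mm 0.14, IAPLTR1_Mm 0.13, MMERGLN-int 0.06 (-0.27 outside genes), IAPEz-int 0.05, B2_Mm2 -0.05 (0.06 when scaled on repeat counts) and L1_Mus1 -0.12 (-0.01 when scaled on repeat counts). Over copies outside genes, edgeR did not call RLTR4_Mm (adjusted p = 0.13), IAPEz-int (0.672), B2_Mm2 (0.992) or L1_Mus1 (0.0748). IAPLTR1a_Mm, IAPLTR2_Mm, RLTR4_MM-int and IAPLTR1_Mm stayed called there with the same sign.

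Repeat entries of the rRNA class, kept out of the repeat tests, stood above the highest DMSO library (810.5) in all 3 libraries labelled AG120+IFNγ, at 1531 ± 314 CPM (1246 to 1867).

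In the libraries labelled AG120+IFNγ, the genes that IFNγ alone raised at least 2-fold were, but for 2, not called higher than with AG120, while smaller changes went either way against IFNγ alone: cholesterol synthesis rose in 14 and 15 of 20 genes, and histone demethylases rose in 9 of 19 where IFNγ alone lowered 10. The medians of these lists in AG120+IFNγ against AG120 were only 0.09 and 0.07, and the balance of directions in that comparison follows the scaling. Saturation by AG120 is argued against for the 54 genes that IFNγ raised and that stood at least 2-fold lower with AG120 than with IFNγ. Against DMSO their median was 4.8 with IFNγ and 1.85 with AG120, which left room to rise, but it was -0.17 in AG120+IFNγ against AG120. Of them, 1.9% were called higher with AG120+IFNγ than with AG120. That share could not have been large, since 2 of all 238 were, so it adds nothing. IFNγ missing from these cultures, or libraries with wrong labels, was not decided: the 0.8% of 238 induced genes called higher is the pattern itself, and whether IFNγ moved any of the 1294 genes called in all was not tested. Cells made refractory by AG120 was not decided either. Socs1, an inhibitor of interferon receptor signalling, rose by 2.59 ± 0.13 with AG120 but is itself interferon-induced (2.66 with IFNγ alone). Usp18, the other feedback inhibitor in this prediction, rose by 7.44 ± 0.07 with AG120 and by 2.4 ± 0.13 with IFNγ alone, so it is interferon-induced as well. Ifngr1 (0.57) and Ifngr2 (0.93) stood higher, and RNA counts cannot show a block at the protein level. These last explanations, a technical and a biological one, both stay open.

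The rise of IAP and other LTR subfamilies with AG120 held for IAPEz-int when libraries were scaled on repeat counts (5.87) and over copies outside annotated genes (6.20). The lowest LTR total with AG120 was 7.01 times the highest without, more than movement of reads between similar copies within the class can give. Loss of silencing by DNA methylation, a hypothesis, has the value it needs, with 26 of 26 methylation-silenced germline genes called higher, but methylation was not measured here. It was found and tested on the same data. With IFNγ alone, which raised interferon genes, 1 germline gene rose and 2 fell, and IAPEz-int moved by 0.06.

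The largest gene-level rises with AG120 might hold repeat reads counted to genes. Of the 97 annotated among the 100 genes that rose most, 8.2% (exact 95% interval 3.6 to 15.6%) have exons overlapping LTR subfamilies that rose at least 2-fold, against 1.0% of tested annotated genes. That meets neither the bound set for this explanation, over 50%, nor the bound against it, under 2 times the background. It stays open for the 8 genes with such an overlap. The other annotated genes have no exon in these subfamilies, which argues against this route for them, as far as the GENCODE M21 exons go. An overlap of 1 base counted, and 3 of these 8 genes, AC134333.1, Gm3883 and BC035044, overlap by 1, 6 and 16 bases. Wdr31 (7.42) and Sirt5 (7.10) are also among the 8, and the genes named here were chosen after their values were seen.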

How the results depend on the processing

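In this part the minimum log2 fold change of 1 for subfamilies and the class totals without the FordPrefect copy were chosen after seeing the data. No named gene or single copy changed direction in any alternative run; of called named genes, 1 of 145 (AG120 against DMSO), 10 of 127 (IFNγ against DMSO), 2 of 143 (AG120+IFNγ against IFNγ), 31 of 79 (AG120+IFNγ against AG120) and 10 of 120 (interaction) lost the call in at least 1. In the same order, 1 of 27, 18 of 25, 3 of 28, 12 of 21 and 11 of 19 called named subfamilies did, and of 6 single copies 1 for IFNγ against DMSO and 5 for AG120+IFNγ against AG120. In this order of comparisons, a minimum log2 fold change of 1 left 2978, 260, 2957, 27 and 292 genes and 74, 5, 65, 7 and 7 subfamilies, by construction fewer. A replicate block, whose numbers do not pair the libraries (same-number correlations -0.11 to 0.08), gave 11714, 4407, 11738, 1219 and 3502 genes. Counts with each library left out were 11223 to 11446, 3829 to 4056, 11292 to 11475, 765 to 1459 and 3172 to 3457 genes, and 89 to 153 single copies for AG120+IFNγ against AG120. For the values that follow the cause was not tested. AG120+IFNγ against AG120 gave 2294 genes with library size alone. Scaling on repeat counts gave 72 subfamilies for IFNγ against DMSO, and 202 and 122 single copies for AG120+IFNγ against AG120; copies outside genes gave 58, 121 and, for the interaction, 25. Lists numbered 28 with fry for AG120+IFNγ against IFNγ and 7 with an estimated correlation for AG120+IFNγ against AG120, and the endothelial and mural list turned down with fry (adjusted p = 3.17e-05 for AG120 against DMSO, 3.5e-06 for AG120+IFNγ against IFNγ).

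The AG120 effect on class totals was 0.014 for LINEs without TMM (adjusted exact p = 0.645). As a share of repeat counts it was -1.241 for LINEs (0.00667) and -0.156 for DNA transposons (0.1), and without the FordPrefect copy -0.021 for DNA transposons (0.295). The IFNγ effect as a share was 0.028 for LTR elements (0.02), -0.15 for LINEs (0.06) and -0.08 for SINEs (0.1), with the block -0.176 for LINEs and -0.107 for SINEs (0.0781 each, with unadjusted p at 0.0312, the smallest the block can give), and without the copy -0.131 for DNA transposons (0.01). With each library left out, the AG120 effect was 1.369 to 1.377 for all repeats, 2.915 to 2.925 for LTR elements, 0.127 to 0.137 for LINEs, -0.07 to -0.062 for SINEs and 1.206 to 1.228 for DNA transposons, and the IFNγ effect -0.005 to 0.004 for LTR elements.

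Subfamilies that changed direction outside genes were, for AG120 against DMSO, B1_Mm 0.01 and B2_Mm2 0.20; for AG120+IFNγ against IFNγ, B1_Mm 0.03, B2_Mm2 0.20 and MT2_Mm -0.01. For AG120+IFNγ against AG120 they were FordPrefect -0.24, MER53 -0.23 and MMERVK10C-int 0.02, for IFNγ against DMSO MMERGLN-int 0.25, RLTR13D3 -0.10, RLTR34D_MM -0.13 and RLTR6-int -0.23, and for the interaction B2_Mm2 0, FordPrefect -0.19, MMERGLN-int -0.27 and RLTR13D3 0.08. Scaling on repeat counts shifts all subfamilies of a library alike by construction (IAPEz-int from 0.11 to 0.32 in AG120+IFNγ against AG120), so values near 0 change sign together. Direction changed for AG120+IFNγ against AG120 in B1_Mm 0.11, B2_Mm2 0.09, MERVL-int 0.05, MMERGLN-int 0.18, MMERVK10C-int 0.14, MMVL30-int 0.20, MT2_Mm 0 (adjusted p = 0.991), MuRRS-int 0.02, RLTR10C 0.18 and RLTR6-int 0.16. The same scaling changed it for IFNγ against DMSO in B1_Mm 0.03, B2_Mm2 0.03, MERVL-int 0.01 and MMERGLN-int 0.01, and for the interaction in B1_Mm 0.08, B2_Mm2 0.06 and MMERVK10C-int 0.10.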

Other observations

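Genes outside the rule for named genes, chosen after their values were seen, bear on interferon feedback. Socs1 rose by 2.59 ± 0.13 with AG120 and by 2.66 ± 0.13 with IFNγ. The receptor chains Ifngr1 and Ifngr2 stood 0.57 and 0.93 higher with AG120, and the kinases Jak1 and Jak2 at 0.08 and -0.15. In AG120+IFNγ against AG120, Socs1 stood at -0.07 (adjusted p = 0.787).

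The pseudogene CT010467.2 (chromosome 17, 39811786 to 39812022) took 2.13 to 2.76% of gene counts in libraries without AG120, 3.68 to 4.12% with AG120 and 5.59 to 5.79% in the libraries labelled AG120+IFNγ. The FordPrefect copy in Gm26917 lies on the same chromosome (39842998 to 39843163), and FordPrefect rose by 0.60 in AG120+IFNγ against AG120. Repeat entries of the rRNA class stood at 1531 ± 314 against 182.6 ± 84.9 CPM there. Whether these rises share a source was not tested.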
